A study of Mus musculus with 18 samples.

How the data were processed

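Expression was measured with spotted mouse cDNA arrays of 17327 spots in 18 samples of differentiating i-Mixl1 embryonic stem cells, 3 with and 3 without DOX at each of 3 days. Total RNA was amplified linearly in 1 round and labelled with Cy3 or Cy5, per the labels' protocols. The deposited day tables hold, per the file headers, the intensity of each spot in the 635 and 532 nm channels of an array as median foreground minus background on the linear scale, with no normalization. They also hold a score per spot and channel, the signal-to-noise ratio, and spot flags, per the file headers. The authors left out spots on flags, signal-to-noise ratio and negative values, set all 153 kept values not above 0 to 10, and scaled both channels of the 3 arrays of a day to 1 common mean, as the deposited values show. Days were scaled separately, so the deposited intensity values were not compared between days. The deposited ratio, or fold, of each array is the scaled 635 value over the scaled 532 value, and the deposited p-value is from a one-way ANOVA on the linear values. By these tables the authors called 112 probes up and 98 down at day 2, 304 and 631 at day 3, and 449 and 773 at day 4. The rules behind these calls are in part unknown. The named upward fold filter was looser at day 4 than at days 2 and 3, so the up counts are not directly comparable.

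Each column of the value table equalled a scaled channel of a day table within 1e-06: the DOX columns equalled the 635 channel and the control columns the 532 channel, for all 18 samples. The labels give Cy3 to DOX samples and Cy5 to controls, which would be the other way round. The scale and centring of the value table are known from this match, and its direction is not. Its column medians ran from 724 to 1257. Ratios are therefore given as the 635 (red) over the 532 (green) channel. The scanner columns hold no separate background, so the alternative without background correction was not run.

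Values were processed in R 4.3.3 with limma 3.58.1. Spots with a flag of -75 or below were left out. Background was modelled with normexp and an offset of 50 on all spots, control spots had no weight in the loess, and ratios were normalized within each array by 1 loess curve. One linear model of the 9 log2 ratios with a term per day, and 6 residual degrees of freedom, gave the comparison of each day and the differences between days through empirical Bayes moderation, with all days sharing 1 estimate of the spread. The array is a block in these ratios. The time course used single-channel log2 values after loess within and Aquantile between arrays, over 9 samples of a channel. Probes passed at a Benjamini-Hochberg adjusted p of 0.05 over all probes tested; all tests were two-sided. A channel was taken as not well above background where its signal-to-noise ratio was under 1.4 on all 3 arrays of a day. A bound then sets the mean of the other group against the higher of the lowest signal among probes past the limit and the dim probe's own, from single-channel values open to dye bias. Where the dim probe's own signal is the higher, the bound equals the ratio of the means. A bound allows for background in the dim channel and not for sampling error.

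The 25 gene lists were those of the primitive streak and mesendoderm, definitive endoderm, paraxial mesoderm, cardiac mesoderm, hematopoietic, endothelial, trophoblast, extraembryonic endoderm, epithelial, mesenchymal, pluripotency, primed epiblast, neuroectoderm, Hox and Cdx, and fibroblast genes, targets of Nodal and activin, BMP and Wnt, and genes of glycolysis and hypoxia, oxidative phosphorylation, heat shock and unfolded protein response, mitochondrial stress, p53 and apoptosis, cell cycle and ribosomal proteins. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over lists, where at least 5 members were measured on all arrays, which left 20 lists. Some lists share members, so their results are not independent. Eomes and Tdgf1 are in both the Nodal and the primitive streak list, and Gata2 is in both the BMP and the hematopoietic list. The tests, the lists, the panel, the rule for named genes and most alternatives were chosen before the data were examined. Named genes are the 10 largest each way per day past the test and alike in sign on all 3 arrays, the 5 largest each way per difference between days, the 8 largest each way per time comparison, up to 4 members past the test per list, and the panel where measured. Unnamed, RIKEN and EST names were passed over, and 1 gene that met these rules is not reported here.

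Symbols came from the array tables: 3989 of 8744 probes with a symbol carried a current one, 3903 were updated from older names through the RefSeq gene table and 852 kept the name of the table, among them Nrp, Ndr2, IRS-3 and SDF-1-beta.

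The procedure was tested on simulated data made from the arrays' own intensities, bias curves and spread. With 67, 67 and 66 of 15247 probes changed by 1.5, 2 and 4-fold, the day 4 comparison recovered 65.7% of those at 1.5-fold, 95.5% at 2-fold and 98.5% at 4-fold, with 6 of 15017 unchanged probes called, and day 4 minus day 2 recovered 35.8, 76.1 and 98.5%. The time comparison of day 4 with day 2 recovered 1.49, 20.9 and 83.3%. The simulated noise was independent between probes and held no dye or position effect of single probes. These rates therefore do not cover false calls from such effects. Alternatives covered background, normalization, dim probes, the test, the replicate block, the value table and leaving out each array. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.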

Results

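Gene expression was measured in embryoid bodies grown from i-Mixl1 mouse embryonic stem cells, a line named for the homeobox gene Mixl1, with or without doxycycline (DOX). DOX was added at 0.1 ug/ml 1 day after plating, and RNA was taken at day 2, day 3 and day 4, with 3 biological replicates in each of the 6 groups. The 18 samples were hybridised in pairs to 9 arrays of spotted mouse cDNA clones, 3 arrays per day, each carrying a DOX and a control sample of the same day and replicate number. Of 17327 spots, 15247 were gene probes, and 8744 of these carried one of 5529 different gene symbols. The median intensity of a sample ran from 209 to 491, and 54.3 to 70.1% of the gene probes of a sample reached the signal-to-noise limit of 1.4. By channel this share was 54.3 to 65.6% in the red and 62.0 to 70.1% in the green, and the red was lower on each array. Gene probes with values not above 0 numbered 1993 to 4132 in the red and 809 to 2224 in the green, again with more in the red on each array. Log2 ratios of arrays of the same day correlated across probes with r between 0.52 and 0.73, and those of day 2 with day 4 arrays with r between 0.11 and 0.31; probes are not independent replicates. The number of arrays, 3 per day, limits the precision of every value.

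The direction of the ratios was not settled by the labels and the deposited tables together. All ratios are the red over the green scanner channel of the same array, and higher and lower mean higher and lower in the red channel. By the value table, the red channel holds the DOX sample, so that higher means higher with DOX; by the dyes in the labels, Cy3 for DOX and Cy5 for control, higher means higher in the control. Every array ran the same way, so that dye and treatment were confounded within a day, while a dye effect that is constant for a probe drops out of a difference between days. No probe on the array was named Mixl1, so its level was not analysed here. Values after ± are standard errors from limma over 3 arrays per day, and each gene is represented by its brightest probe.

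The day 2 comparison asked which genes differed between the DOX and control samples soonest after DOX was added. Podxl, a sialomucin of the apical cell surface, was 8.38-fold higher (log2 3.07 ± 0.092, n = 3 arrays), and Ccnd2, cyclin D2, was 4.88-fold higher (log2 2.29 ± 0.12). Dimmer probes of Podxl gave log2 2.87 and 1.41, and its dimmest did not pass (0.095). A dimmer probe of Ccnd2 gave log2 1.28, and its dimmest did not pass (0.074). Eomes, a T-box transcription factor of the primitive streak, was 1.96-fold higher (log2 0.97 ± 0.11), and Klf5, a zinc finger factor of pluripotent cells, was higher by 0.97 ± 0.089. Upp1, which cleaves uridine, was higher by 1.85 ± 0.090, from a clone whose PCR is noted as giving no product. Lmo1, a LIM-domain transcription regulator, was higher by 1.27 ± 0.096, and Hebp1, a heme-binding protein, 2.30-fold. Coch, a secreted matrix protein, was higher by 1.06 ± 0.10, and Tnfrsf19, a TNF receptor family member, by 1.06 ± 0.084. Kifc3, a kinesin, was higher by 1.01 ± 0.14 and the imprinted gene Mest by 0.98 ± 0.075. Adjusted p for the 10 largest higher genes ran from 1.71e-11 to 3.21e-04.

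The 10 largest lower genes at day 2 were dim. In all 10 the red channel was not well above background on any day 2 array, so that only bounds could be given, and for Rubcn, dim in both channels, no fold. All 10 lay in print blocks 21, 24 or 25, and, as for every gene within a day, a dye effect cannot be separated from treatment. Prim2, a subunit of DNA primase, was at least 2.62-fold lower, Agr2, a protein disulfide isomerase of secretory cells, at least 2.41-fold, IRS-3, an insulin receptor substrate, at least 2.32-fold and Smoc1, a matrix protein, at least 2.27-fold. Tank, Gatm, Col6a4, Nr2f1 and Pcca were lower by at least 2.22, 2.06, 2.04, 1.95 and 1.79-fold. The clones of Smoc1 and Gatm are noted as giving no PCR product, and the other probe of Col6a4 did not pass. A dimmer probe of Agr2 was lower too (-0.86), while another did not pass (0.11, adjusted p = 0.559). The lower probes of Agr2, Nr2f1 and Col6a4 have clone names ending in D07 or E07. The probes of Agr2 and Col6a4 that did not pass have other endings. Both lower Agr2 probes end in E07, so they are no independent support of each other. An effect tied to clone position was not tested. Adjusted p for these 10 genes ran from 2.00e-06 to 1.66e-04. Among brighter genes, 3 list members were lower: Trh, the thyrotropin-releasing hormone precursor (-0.67 ± 0.10), the DNA methyltransferase Dnmt3a (-0.53 ± 0.085) and cyclin E1, Ccne1 (-0.31 ± 0.079).

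Of the 20 gene lists tested at day 2, 3 passed, all of them higher: Nodal and activin targets (camera, adjusted p = 0.00966), primitive streak and mesendoderm genes (adjusted p = 0.0214) and BMP targets (adjusted p = 0.0399). With an estimated correlation none of the 3 passed, with adjusted p = 0.244 with an estimated correlation for each. The Nodal and activin targets had 2 of 7 measured members higher, 0 lower and 5 not called (2 higher and 0 lower adjusted over the list alone), with Eomes and Pmepa1 (0.55 ± 0.13), an inhibitor of TGF-beta signalling, past the test. The primitive streak list had 1 of 7 measured members higher, 0 lower and 6 not called (1 higher and 0 lower adjusted over the list alone). That member was Eomes, which is also in the Nodal and activin list, so these lists are not independent. The BMP targets had 2 of 8 measured members higher, 0 lower and 6 not called (3 higher and 1 lower adjusted over the list alone), with Id3 higher by 0.70 ± 0.083 and Id4 by 0.52 ± 0.11, both inhibitors of basic helix-loop-helix factors. Single members of other lists were also higher: Rspo3, an enhancer of Wnt signalling, by 0.63 ± 0.092, Irx3 by 0.59 ± 0.11, Hoxb1 by 0.47 ± 0.083, Lamc1 by 0.44 ± 0.082, Krt8 by 0.42 ± 0.11 and Col1a2 by 0.63 ± 0.11. The other probes of Hoxb1, Lamc1, Krt8 and Col1a2 did not pass at day 2 (for Krt8, adjusted p = 0.0651, 0.460 and 0.268 against 0.0466).

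In all, 503 of 15246 probes passed at day 2, 211 higher and 292 lower, and 2656 had an unadjusted p under 0.05. The count fell to 204 without replicate 1 and to 264 without replicate 3. The share of higher probes was 41.9%, against 68.9% of 122 probes with plain background subtraction, 72.6% of 157 with the scaling of the value table, 64.5% of 245 probes above the median intensity and 31.4% without replicate 1.

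The day 3 comparison asked the same a day later. Nrp, named as neuropilin, a co-receptor for semaphorins and VEGF, was at least 5.72-fold higher, with the green channel not well above background on any day 3 array (adjusted p = 1.23e-07). Dkk1, a secreted Wnt antagonist, was 5.64-fold higher (log2 2.50 ± 0.11, n = 3 arrays), Cdh2, N-cadherin, 4.25-fold (log2 2.09 ± 0.10) and Gata4, a transcription factor of heart and endoderm, 4.03-fold (log2 2.01 ± 0.11). Coch was higher by 2.34 ± 0.10 and Ctla2a, a cysteine protease inhibitor, by 2.27 ± 0.17. Podxl was higher by 2.14 ± 0.092, the growth factor Igf2 by 1.74 ± 0.097 and Lmo1 by 1.71 ± 0.096. Ddx6, an RNA helicase, was higher by 1.81 ± 0.47, the widest error among the 10 largest higher genes. Adjusted p for these genes ran from 1.11e-09 to 0.0144.

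Lower at day 3 were Uchl1, a ubiquitin hydrolase, 2.97-fold (log2 -1.57 ± 0.084), Bnip3, a mitochondrial protein induced by hypoxia, 2.68-fold (log2 -1.42 ± 0.098, from a clone noted as giving no product), and Bmerb1, 2.55-fold (log2 -1.35 ± 0.084). The red channel was not well above background on any day 3 array for St8sia2, Calb1, Gatm, Slc52a3, Prim2 and Agr2, which were at least 2.40, 2.12, 1.96, 2.13, 2.43 and 2.16-fold lower. Il10ra was not well above background in either channel. These 7 lay in print block 21, or 25 for Prim2. The clone of Gatm is noted as giving no product and that of Slc52a3 as multiple bands, and the other probes of St8sia2, Calb1 and Gata4 did not pass at day 3. A dimmer probe of Agr2 was lower at day 3 too (-1.63), while another did not pass (0.15, adjusted p = 0.229). The lower probes of Agr2, St8sia2 and Calb1 have clone names ending in E07, and their probes with other endings did not pass. Adjusted p for the 10 largest lower genes ran from 9.95e-09 to 5.48e-05. Of the panel chosen before the data were examined, Eomes was higher by 0.88 ± 0.11 and Gata1, a transcription factor of red cell precursors, was higher (adjusted p = 0.00426) with the green channel not well above background. The fitted ratio of Pdgfra was 0.88 ± 0.079, above 0 on all 3 arrays, and that of Cdh1 was -0.24 (adjusted p = 0.0396). Neither was well above background in either channel at day 3. Lower were Pou5f1, which encodes Oct4 (-0.76 ± 0.13), Epcam, an epithelial adhesion molecule (-0.60 ± 0.080), and, by its brightest probe, Cer1, a secreted antagonist of Nodal and BMP (-0.27 ± 0.083). None of the other 6 probes of Cer1 passed at day 3, and one of them nearly as bright gave 0.014 (adjusted p = 0.928).

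Of the 20 lists, 8 passed at day 3. The BMP targets were higher as a group (adjusted p = 6.48e-09). The list had 8 of 8 measured members higher, 0 lower and 0 not called (8 higher and 0 lower adjusted over the list alone): Id4 (1.47 ± 0.11), Gata3 (1.35 ± 0.12), Tbx3 (1.04 ± 0.086) and Hand1, at least 2.26-fold. Trophoblast genes were higher (adjusted p = 5.87e-05). The list had 5 of 9 measured members higher, 0 lower and 4 not called (6 higher and 1 lower adjusted over the list alone). Among them were the imprinted genes Phlda2 (1.54 ± 0.090) and Peg10 (1.04 ± 0.10). Wnt targets were higher (adjusted p = 3.11e-04). The list had 4 of 5 measured members higher, 0 lower and 1 not called (4 higher and 0 lower adjusted over the list alone): Dkk1, and Apcdd1 (1.19 ± 0.10), another Wnt antagonist. Pluripotency genes were higher (adjusted p = 0.00155). The list had 7 of 13 measured members higher, 1 lower and 5 not called (8 higher and 1 lower adjusted over the list alone): Klf5 (1.33 ± 0.089), Tbx3 and Zfp42 (0.76 ± 0.076), which encodes Rex1, were higher, and Pou5f1 was lower. Primitive streak genes were higher (adjusted p = 0.00219; adjusted p = 0.0904 with an estimated correlation). The list had 4 of 7 measured members higher, 1 lower and 2 not called (5 higher and 1 lower adjusted over the list alone), among them Mesp2 (1.12 ± 0.098), a segmentation factor of the mesoderm, and Tdgf1 (0.41 ± 0.098), the Nodal co-receptor Cripto. A dimmer probe of Mesp2 was higher too at day 3 (0.71), while its remaining probes did not pass. Mesenchymal genes were higher (adjusted p = 0.00851; adjusted p = 0.404 with an estimated correlation). The list had 5 of 11 measured members higher, 1 lower and 5 not called (6 higher and 2 lower adjusted over the list alone), led by Cdh2 and the filament protein Vim (0.57 ± 0.097). Extraembryonic endoderm genes were higher (adjusted p = 0.0462; adjusted p = 0.136 with an estimated correlation). The list had 5 of 12 measured members higher, 0 lower and 7 not called (5 higher and 0 lower adjusted over the list alone), among them the basement membrane genes Col4a1 (0.47 ± 0.12) and Lamb1 (0.41 ± 0.10), whose other probes did not pass.

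The glycolysis and hypoxia genes were lower as a group at day 3 (adjusted p = 6.48e-09). The list had 0 of 15 measured members higher, 12 lower and 3 not called (0 higher and 13 lower adjusted over the list alone). Bnip3, the phosphofructokinase Pfkl (-0.70 ± 0.091), the mutase Pgam1 (-0.68 ± 0.10) and the glucose transporter Slc2a1 were among the lower members. The hypoxia-induced peptide Adm was at least 1.79-fold lower. With an estimated correlation 5 of the 8 lists passed: BMP targets, glycolysis and hypoxia, trophoblast, Wnt targets and pluripotency. Of lists too small to test, the paraxial mesoderm genes had 4 of 5 measured members higher, 0 lower and 1 not called (4 higher and 0 lower adjusted over the list alone), with Rspo3 (1.49 ± 0.092), Mesp2 and Cited1 (1.09 ± 0.11) among them. The primed epiblast genes had 1 of 4 measured members higher, 3 lower and 0 not called (1 higher and 3 lower adjusted over the list alone), with the DNA methyltransferases Dnmt3b (-1.18 ± 0.16) and Dnmt3a (-0.74 ± 0.085) and the homeobox gene Otx2 (-0.69 ± 0.14) lower. The neuroectoderm list did not pass (adjusted p = 0.501), with Irx3 higher by 1.23 ± 0.11 and Tubb3 (-0.68 ± 0.099) and Nes (-0.56 ± 0.11) lower.

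At day 3, 3070 of 15247 probes passed, 1394 higher and 1676 lower. The count fell to 1934 without replicate 1 and to 1596 without replicate 2.

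**Figure D1:**
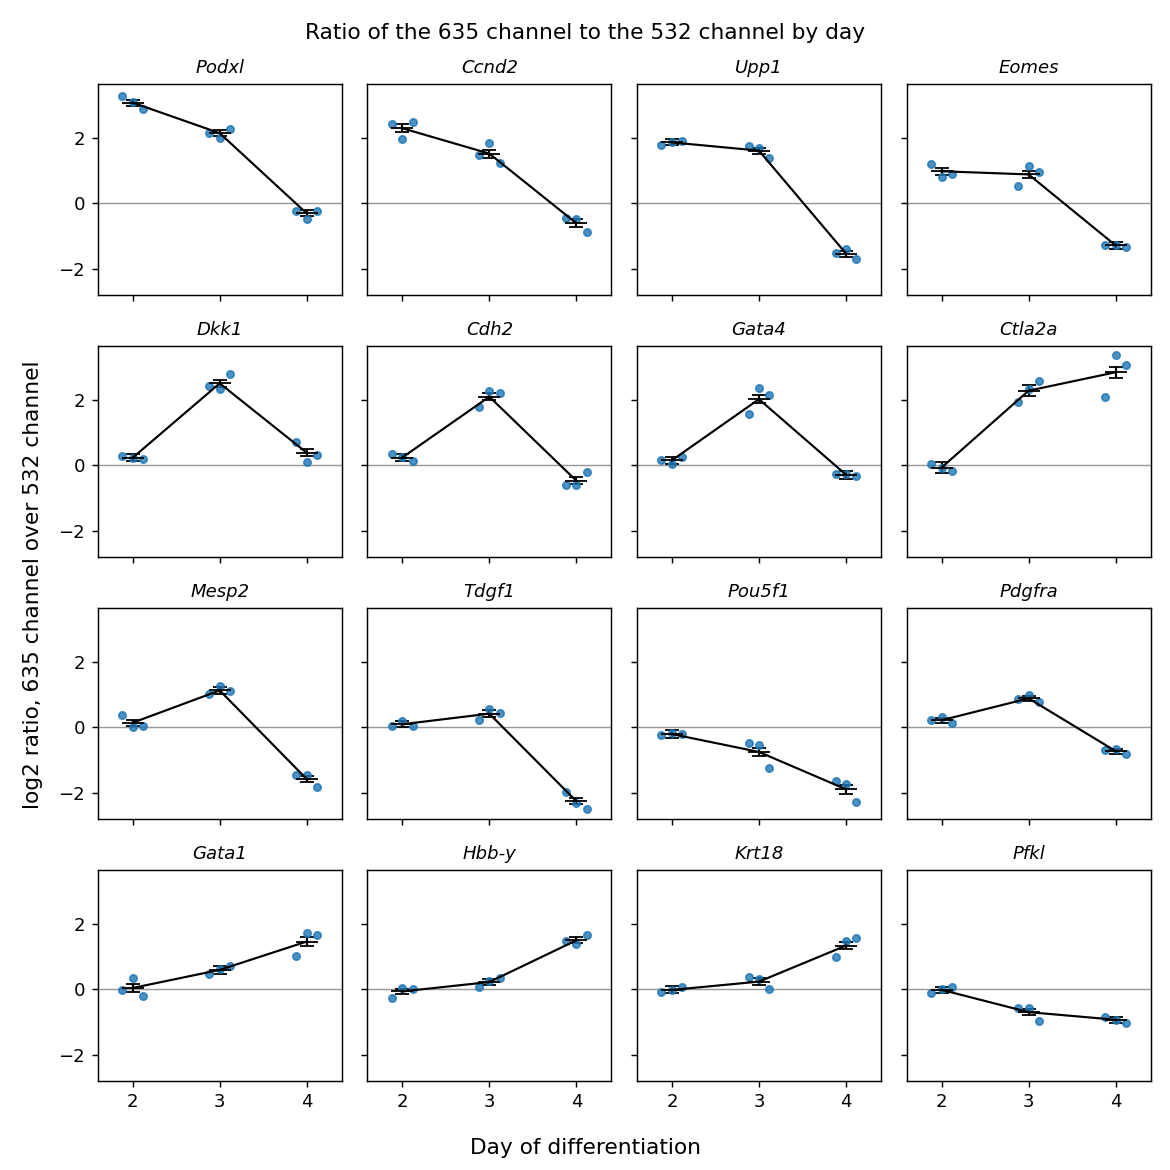
Log2 ratio of the red channel to the green channel for 16 named genes at day 2, day 3 and day 4; points are the 3 arrays of a day, black bars the mean and its standard error from limma, and lines join the means. Podxl, Ccnd2, Upp1 and Eomes lay above 0 at day 2 and day 3 and below 0 at day 4, while Ctla2a, Gata1, Hbb-y and Krt18 were highest at day 4.

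The day 4 comparison asked for the state at the end of the course. Ctla2a was 7.13-fold higher (log2 2.83 ± 0.17, n = 3 arrays), Tdo2, a tryptophan-degrading enzyme, 3.61-fold (log2 1.85 ± 0.097), and Ttr, the thyroid hormone carrier made by visceral endoderm, 3.05-fold (log2 1.61 ± 0.12). Hbb-y, an embryonic beta globin, was at least 2.81-fold higher and Gata1 2.74-fold higher (log2 1.45 ± 0.13). Tdgf1 was 4.79-fold lower (log2 -2.26 ± 0.098), Pou5f1 3.72-fold lower (log2 -1.90 ± 0.13), Mesp2 3.00-fold lower (log2 -1.59 ± 0.098) and Eomes 2.45-fold lower (log2 -1.29 ± 0.11). A dimmer probe of Mesp2 was lower too (-1.61), while its remaining, dimmer probes did not pass (-0.12, -0.20, 0.077 and -0.10).

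Other large higher genes at day 4 were Cited1 (1.41 ± 0.11), a transcription co-activator, Krt18 (1.33 ± 0.11), a keratin of simple epithelia, Adgra2 (1.32 ± 0.13), an adhesion receptor of endothelium, and Lgals1 (1.30 ± 0.10), a galectin. The other largest lower genes included Dbt (-2.08 ± 0.078), a subunit of the branched-chain keto acid dehydrogenase, Upp1 (-1.54 ± 0.090) and Rara (-1.42 ± 0.090), a retinoic acid receptor. Also lower were Ndr2 (-1.36 ± 0.097), named as N-myc downstream regulated, Gimap3 (-1.34 ± 0.11) and Aldh1a2 (-1.30 ± 0.098), which makes retinoic acid, with Prim2 at least 1.93-fold lower. The other probes of Dbt, with log2 0.35 and 0.069, were dimmer and did not pass; nor did the other probe of Adgra2. Adjusted p ran from 1.37e-08 to 3.95e-06 for the higher genes named and from 5.07e-10 to 5.17e-07 for the 10 largest lower ones. Of the panel, Pdgfra, a growth factor receptor of mesoderm, was lower (-0.73 ± 0.079), and neither Cer1 (0.16 ± 0.083, adjusted p = 0.217) nor Epcam (0.16 ± 0.080, adjusted p = 0.197) passed. A dimmer probe of Cer1 was lower (-0.60, adjusted p = 6.90e-04). T and Cdh1 were not well above background in either channel at any day.

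Of the 20 lists, 10 passed at day 4. Epithelial genes were higher (adjusted p = 6.75e-05; adjusted p = 0.0592 with an estimated correlation). The list had 7 of 15 measured members higher, 2 lower and 6 not called (9 higher and 2 lower adjusted over the list alone): Krt18, Krt8 (1.10 ± 0.11), Krt19 (0.91 ± 0.12) and the desmosomal Pkp2 (0.95 ± 0.091) were among those higher. BMP targets were higher (adjusted p = 2.42e-04; adjusted p = 0.0592 with an estimated correlation). The list had 5 of 8 measured members higher, 0 lower and 3 not called (6 higher and 0 lower adjusted over the list alone): Gata2 (1.23 ± 0.10), Gata3 (1.02 ± 0.12), Id2 (0.92 ± 0.13) and Id3 (0.74 ± 0.083). Hematopoietic genes were higher (adjusted p = 0.00174; adjusted p = 0.0719 with an estimated correlation). The list had 4 of 7 measured members higher, 1 lower and 2 not called (4 higher and 1 lower adjusted over the list alone): Hbb-y, Gata1, Gata2 and the embryonic alpha globin Hba-x (1.15 ± 0.14). Wnt targets (2 higher, 0 lower and 3 not called of 5; 3 and 0 adjusted over the list alone) and extraembryonic endoderm genes (5 higher, 1 lower and 6 not called of 12; 5 and 1 adjusted over the list alone) were higher, each with adjusted p = 0.0390 and adjusted p = 0.138 with an estimated correlation. Apcdd1 (0.89 ± 0.10) was higher in the former and Ttr and the endocytic adaptor Dab2 (0.86 ± 0.087) in the latter. Trophoblast genes (4 higher, 2 lower and 3 not called of 9; 5 and 2 adjusted over the list alone) and heat shock and unfolded protein response genes (2 higher, 0 lower and 10 not called of 12; 5 and 0 adjusted over the list alone) were higher, each with adjusted p = 0.04999 (adjusted p = 0.147 and 0.189 with an estimated correlation). In the trophoblast list Plac1 was higher by 1.28 ± 0.093 and Tfap2c was lower (-0.73 ± 0.098), and in the heat shock list the chaperones Dnajc3 (0.66 ± 0.098) and Creld2 (0.26 ± 0.082) were higher.

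Lower at day 4 were the glycolysis and hypoxia genes (adjusted p = 2.04e-06). The list had 1 of 15 measured members higher, 10 lower and 4 not called (1 higher and 12 lower adjusted over the list alone): Pfkl (-0.93 ± 0.091), Pgk1 (-0.91 ± 0.14), Aldoa (-0.80 ± 0.090) and Ldha (-0.75 ± 0.11), all enzymes of glycolysis, were lower, and Slc2a1 (0.31 ± 0.084) was higher. Nodal and activin targets were lower (adjusted p = 0.00142; adjusted p = 0.0592 with an estimated correlation). The list had 0 of 7 measured members higher, 4 lower and 3 not called (0 higher and 4 lower adjusted over the list alone): Tdgf1, Eomes, Otx2 (-1.26 ± 0.14) and Pmepa1 (-0.88 ± 0.13). Cell cycle genes were lower (adjusted p = 0.0207; adjusted p = 0.189 with an estimated correlation). The list had 0 of 23 measured members higher, 4 lower and 19 not called (0 higher and 4 lower adjusted over the list alone), among them the centromere histone Cenpa (-0.49 ± 0.079) and Ccne1 (-0.38 ± 0.079). With an estimated correlation, of the 10 lists, 1 passed: glycolysis and hypoxia (adjusted p = 0.0254 with an estimated correlation).

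The remaining lists did not pass at day 4, with adjusted p = 0.0544 for primitive streak, 0.117 for p53 and apoptosis, 0.307 for endothelial and 0.312 for definitive endoderm. Adjusted p was 0.331 for nuclear-encoded oxidative phosphorylation, 0.561 for mesenchymal, neuroectoderm and mitochondrial stress, 0.765 for pluripotency and 0.955 for ribosomal protein genes. Within them the endothelial adhesion molecule Pecam1 was higher by 1.29 ± 0.11, Otx2 was lower in the definitive endoderm list, Cldn6 (0.82 ± 0.088), a tight junction protein, was higher there, and Trp53 (-0.50 ± 0.13) and Mdm2 (-0.49 ± 0.082) were lower in the p53 list. In the mesenchymal list Pdgfra and Cdh2 (-0.48 ± 0.10) were lower and Vim (0.64 ± 0.097) and Pdgfrb (0.69 ± 0.099) higher. The other probes of Cdh2 and Mdm2 did not pass at day 4. The pluripotency list had 3 of 13 measured members higher, 2 lower and 8 not called (6 higher and 2 lower adjusted over the list alone), with Dppa5a (0.74 ± 0.089) higher beside the lower Tdgf1 and Pou5f1. Its median was 0.10 and its mean -0.15, with the test pointing upward. The median of the primitive streak list was 0.0046 and that of the neuroectoderm list 0.12, against means of -0.59 and -0.14. The ribosomal protein list had 1 of 30 measured members higher, 0 lower and 29 not called (1 higher and 0 lower adjusted over the list alone); the test pointed downward with a mean of 0.011. At day 3 the hematopoietic test pointed upward (adjusted p = 0.924) with a mean of -0.028, and at day 2 the mitochondrial stress list had a mean of -0.010 and a median of 0.016. For day 4 minus day 2 the pluripotency list had a mean of -0.27 and a median of 0.034. Of the lists too small to test, paraxial mesoderm had 1 of 5 measured members higher, 3 lower and 1 not called (1 higher and 4 lower adjusted over the list alone), primed epiblast 1 of 4 measured members higher, 3 lower and 0 not called (1 higher and 3 lower adjusted over the list alone), cardiac mesoderm 3 of 4 measured members higher, 0 lower and 1 not called (3 higher and 1 lower adjusted over the list alone), fibroblast 2 of 5 measured members higher, 1 lower and 2 not called (3 higher and 1 lower adjusted over the list alone), and Hox and Cdx 0 of 2 measured members higher, 1 lower and 1 not called (0 higher and 1 lower adjusted over the list alone). Cd44 (1.27 ± 0.088), a hyaluronan receptor, and Tbx20 (0.76 ± 0.085), a cardiac transcription factor, were among the higher members.

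At day 4, 2656 of 15243 probes passed, 1215 higher and 1441 lower. The count fell to 1704 without replicate 2 and to 1145 without replicate 3.

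**Figure D2:**
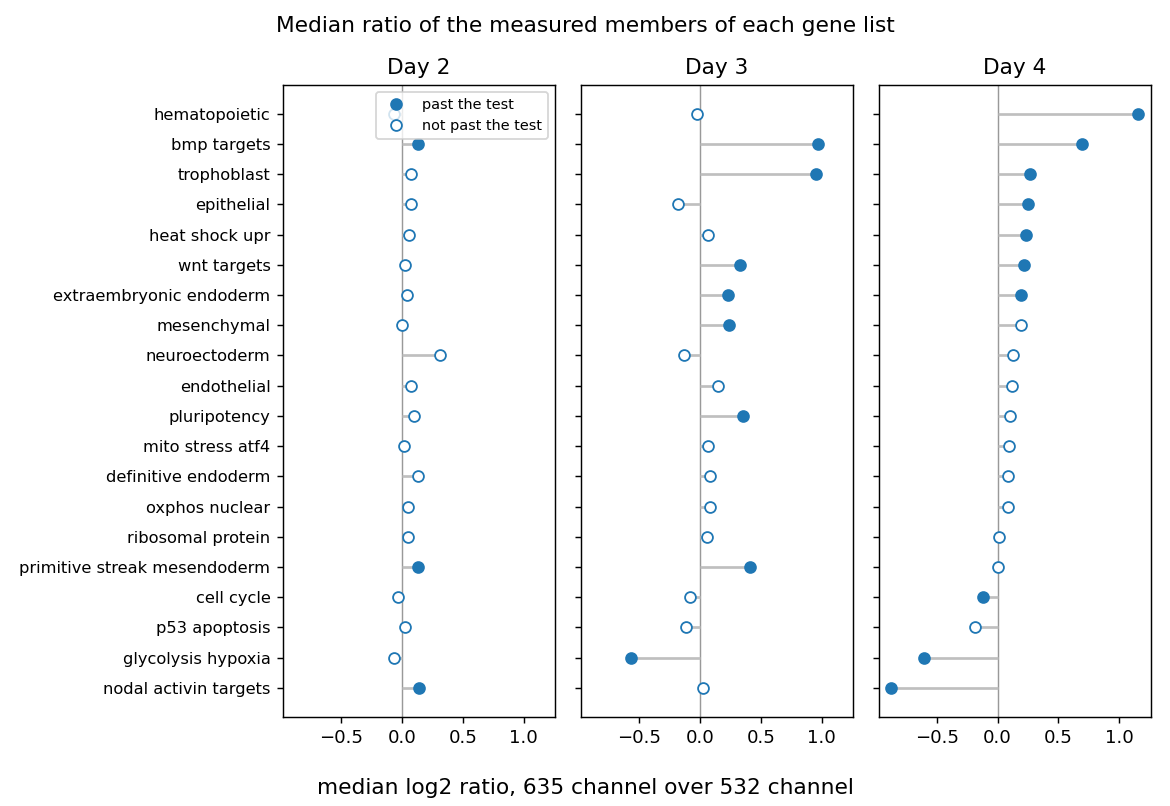
Median log2 ratio of the red channel to the green channel over the measured members of each of the 20 tested gene lists at each day, with filled points for lists past the camera test at an adjusted p of 0.05. The hematopoietic list had its highest median at day 4, 1.15, and the Nodal and activin targets had their lowest there, -0.88.

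The differences between days asked which ratios changed with time, and a dye effect constant for a probe drops out of them. From day 2 to day 4 the ratio of Upp1 fell by 3.39 on the log2 scale (SE 0.13), that of Podxl by 3.38 (SE 0.13), that of Ccnd2 by 2.90 (SE 0.18), that of Tdgf1 by 2.35 (SE 0.14) and that of Eomes by 2.26 (SE 0.15), with n = 3 arrays per day. The ratio of Ctla2a rose by 2.91 ± 0.24, that of Tdo2 by 1.77 ± 0.14, and those of Ttr and Hbb-y by 1.56 ± 0.16 and 1.56 ± 0.13. Adjusted p for these 9 genes ran from 3.56e-10 to 2.24e-05. From day 2 to day 3 the largest changes upward were those of Nrp, Ctla2a, Dkk1 (2.27 ± 0.15), Gata4 (1.87 ± 0.16) and Cdh2 (1.85 ± 0.15), where the other probes of Gata4 and Cdh2 did not pass, and the largest downward those of Ndr2 (-1.46 ± 0.14), Cldn3 (-1.27 ± 0.15), Uchl1 (-1.26 ± 0.12), Bnip3 (-1.26 ± 0.14) and Igfbp5 (-1.04 ± 0.18). From day 3 to day 4 they were those of Igfbp5 (2.02 ± 0.18), Uchl1 (1.91 ± 0.12), Tdo2, the matrix protein Spp1 (1.66 ± 0.12) and Serinc5 (1.53 ± 0.11) upward. Downward they were those of Upp1, Mesp2 (-2.71 ± 0.14), Tdgf1, Cdh2 (-2.57 ± 0.15) and Podxl. Nrp, Ctla2a, Tdo2, Hbb-y and Igfbp5 were not well above background in a channel on at least 1 of the days compared.

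Of the 20 lists, 6 passed for day 4 minus day 2. Epithelial (7 higher, 1 lower and 7 not called of 15; 8 and 1 adjusted over the list alone) and hematopoietic genes (4 higher, 0 lower and 3 not called of 7; 4 and 1 adjusted over the list alone) moved upward, each with adjusted p = 2.70e-04 (adjusted p = 0.0901 and 0.0668 with an estimated correlation). So did BMP targets (adjusted p = 0.0251; adjusted p = 0.130 with an estimated correlation). Nodal and activin targets (adjusted p = 1.12e-05), glycolysis and hypoxia genes (adjusted p = 1.33e-05) and primitive streak genes (adjusted p = 0.00140; adjusted p = 0.0901 with an estimated correlation) moved downward. The Nodal list had 0 of 7 measured members higher, 4 lower and 3 not called (0 higher and 4 lower adjusted over the list alone), the glycolysis list 1 of 15 measured members higher, 7 lower and 7 not called (1 higher and 10 lower adjusted over the list alone), the primitive streak list 0 of 7 measured members higher, 3 lower and 4 not called (1 higher and 3 lower adjusted over the list alone) and the BMP list 2 of 8 measured members higher, 1 lower and 5 not called (5 higher and 1 lower adjusted over the list alone). Eomes and Tdgf1 were among the lower members of both the Nodal and the primitive streak list. With an estimated correlation 2 of the 6 passed, Nodal and glycolysis (adjusted p = 0.0247 with an estimated correlation, each). Gata2 (1.18 ± 0.14), Krt18 (1.35 ± 0.15) and Cldn6 (0.97 ± 0.12) moved upward, and Pmepa1 (-1.42 ± 0.18), Otx2 (-1.40 ± 0.20), Pfkl (-0.91 ± 0.13) and Ldha (-0.86 ± 0.16) downward.

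Of the probes higher at day 2, 116 were also higher at day 3 (19.3 for independent calls) and 9 lower; 40 were also higher at day 4 (16.8 for independent calls) and 50 lower. Of the probes lower at day 2, 170 were also lower at day 4 (27.6 for independent calls) and 11 higher. In all 489 probes changed from day 2 to day 3 (197 upward), 1003 from day 3 to day 4 (600 upward) and 1000 from day 2 to day 4 (520 upward). The first count fell to 257, 260, 257 and 238 without day 2 replicate 1, 2 or 3 or day 3 replicate 2, and the last to 649, 647 and 590 without day 2 replicate 3 or day 4 replicate 2 or 3. Without day 2 replicate 1 it was 317 upward and 318 downward. With the scaling of the value table the upward share was 30.0% in place of 40.3% for day 3 minus day 2 and 35.0% in place of 52.0% for day 4 minus day 2.

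The time course asked how expression changed as the control embryoid bodies differentiated. Each day had its own 3 arrays, so a change between days cannot be told apart from a difference between those arrays. Both channels share the arrays, so their agreement is no independent check. The controls were taken from the green channel, where the value table has them, and each value is given beside that of the red channel, where the dyes in the labels have them. From day 2 to day 4, Hand1, a transcription factor of mesoderm and trophoblast, rose from below background by at least 17.1-fold in the green channel (adjusted p = 8.05e-05) and 23.8-fold in the red channel, and Nrp by at least 18.9 and 30.0-fold. Igf2 rose by 3.91 ± 0.33 on the log2 scale in the green channel and 4.87 ± 0.33 in the red channel (n = 3 samples per day). The others are given in the same order: Bmp4, a growth factor of mesoderm (2.98 ± 0.18 and 3.36 ± 0.18), Rspo3 (3.98 ± 0.32 and 3.10 ± 0.33), Dkk1 (3.79 ± 0.29 and 3.95 ± 0.32), and Gata4 (3.53 ± 0.26 and 3.09 ± 0.35). Dppa5a, a gene of pluripotent cells, fell (-3.56 ± 0.38 and -2.88 ± 0.42), as did Uchl1 (-3.49 ± 0.32 and -2.83 ± 0.34). Gdf3, a TGF-beta family ligand of stem cells, and Dnmt3l, a cofactor of DNA methylation, fell to below background, Gdf3 by at least 18.8 and 19.8-fold and Dnmt3l by at least 25.4 and 18.9-fold. Pdgfra rose by at least 12.8-fold in the green channel but 6.95-fold in the red channel.

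**Figure D3:**
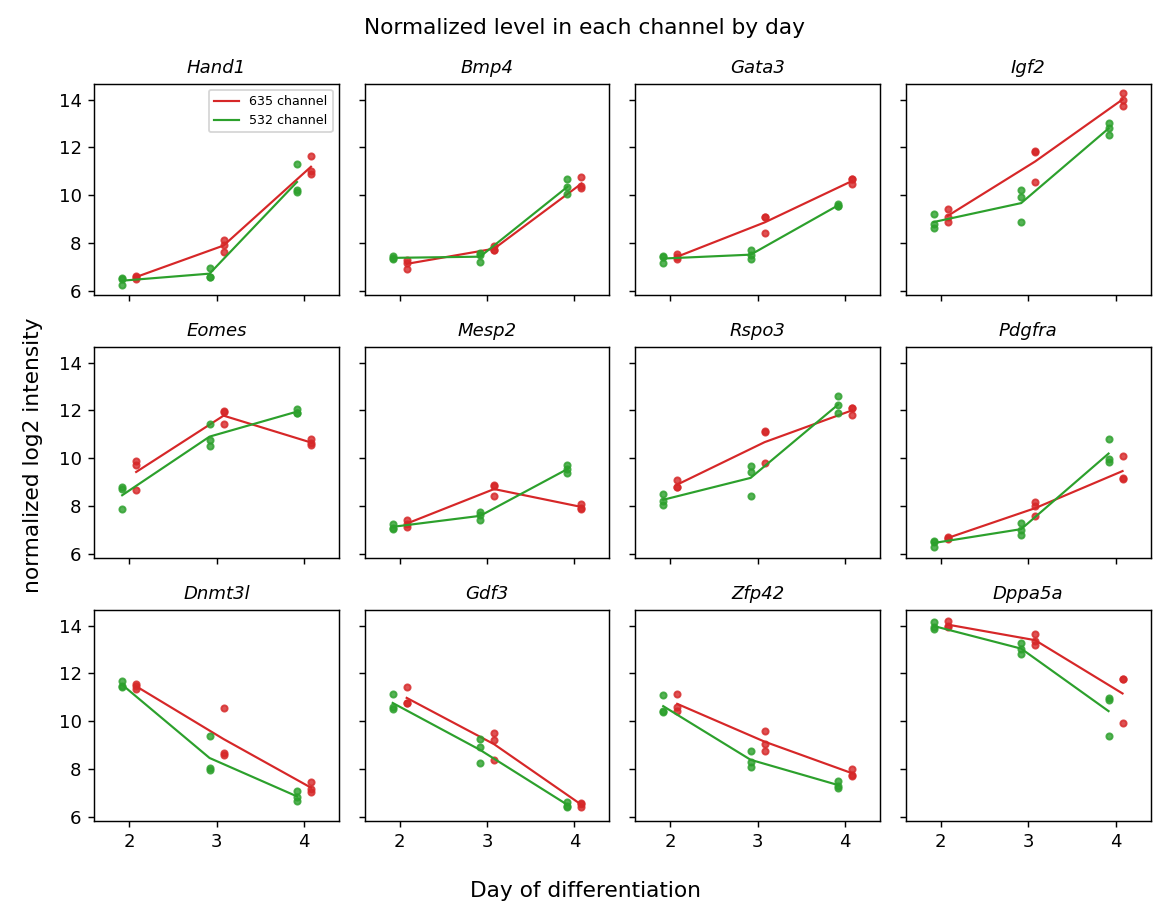
Normalized log2 intensity of 12 named genes in the red channel (red) and the green channel (green) at day 2, day 3 and day 4; points are single samples and lines join the means of 3. Hand1, Bmp4, Gata3 and Igf2 rose and Dnmt3l, Gdf3, Zfp42 and Dppa5a fell in both channels from day 2 to day 4, while Eomes was highest at day 4 in the green channel and at day 3 in the red channel.

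Between day 2 and day 3, Eomes rose by 2.45 ± 0.30 in the green channel and 2.36 ± 0.30 in the red channel. In the same order, rises were seen for the keratin Krt19 (2.47 ± 0.35 and 3.06 ± 0.42), Anxa2, a membrane-binding annexin (2.41 ± 0.23 and 2.43 ± 0.24), Tnfrsf19 (1.67 ± 0.26 and 1.68 ± 0.26), and Nes, the filament protein nestin (1.54 ± 0.25 and 1.33 ± 0.16). Kif24 (1.89 ± 0.19 and 1.28 ± 0.25), a retroviral IAP element (1.71 ± 0.19 and 1.36 ± 0.20) and Stx7 (1.57 ± 0.26 and 1.22 ± 0.28) were the other large rises; Stx7, from a clone noted as giving no product, did not pass in the red channel (adjusted p = 0.0967). Falls were seen for Tcstv1, a gene of preimplantation embryos (-2.70 ± 0.15 and -2.09 ± 0.20), Zfp42 (-2.24 ± 0.24 and -1.58 ± 0.25), Hsf2bp (-2.45 ± 0.24 and -2.47 ± 0.26), Ooep, an egg and early embryo protein (-2.12 ± 0.19 and -1.97 ± 0.23), and Dnmt3l (-3.06 ± 0.35 and -2.21 ± 0.44), where the red channel did not pass for Dnmt3l (adjusted p = 0.0520). Morc1 fell to below background in the green channel, by at least 6.39-fold, and by -2.46 ± 0.28 on the log2 scale in the red channel, and Calml4 to below background in both, by at least 5.15 and 5.65-fold. Between day 3 and day 4, Hand1 rose by at least 14.2-fold in the green channel and by 3.30 ± 0.22 on the log2 scale in the red channel. Nrp rose by at least 19.2-fold in the green channel, against log2 2.57 ± 0.25 in the red channel, and Pdgfra by at least 8.94-fold against at least 2.93-fold. Gata4 rose by 3.26 ± 0.26 in the green channel, against 0.96 ± 0.35 in the red channel (adjusted p = 0.301). Dkk1 rose by 3.07 ± 0.29 against 0.95 ± 0.32 (adjusted p = 0.243). Rspo3 rose by 3.06 ± 0.32 against 1.33 ± 0.33 (adjusted p = 0.0894) and Gimap3 by 3.16 ± 0.26 against 1.16 ± 0.26 (adjusted p = 0.0571). The other probes of Gata4 and Gimap3 did not pass between day 3 and day 4.

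Igf2 rose in both channels between day 3 and day 4 (3.12 ± 0.33 and 2.59 ± 0.33). Uchl1 fell in the green channel (-3.34 ± 0.32), against -1.42 ± 0.34 in the red channel (adjusted p = 0.0823), while Pitrm1 (-2.96 ± 0.29 and -2.11 ± 0.20), Ap2a1, from a clone of questionable quality (-2.65 ± 0.36 and -3.00 ± 0.48), Mkrn1 (-2.65 ± 0.25 and -2.34 ± 0.26), Dppa5a (-2.61 ± 0.38 and -2.23 ± 0.42) and SDF-1-beta, a chemokine (-2.60 ± 0.33 and -2.16 ± 0.33), fell in both. Large falls from day 2 to day 4 were those of Rps7 (-6.85 ± 0.88 and -6.36 ± 0.84), a ribosomal protein gene, Dnaja2 (-6.58 ± 0.45 and -6.01 ± 0.52), a chaperone, and Adprh (-4.40 ± 0.75 and -4.11 ± 0.71), alike in both channels; the other probe of Dnaja2 and the other 29 measured ribosomal protein genes did not pass. In the green and the red channel, Yif1b rose from below background by at least 27.5 and 23.5-fold and Eif2b4 by at least 18.2 and 25.6-fold, and Ppbp fell to below background by at least 12.4 and 13.7-fold, from a clone of questionable quality.

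By list, 5 of 9 measured trophoblast genes rose in both channels from day 2 to day 4, with Gata3 (2.22 ± 0.14 and 3.17 ± 0.20) and Peg10 (2.11 ± 0.27 and 2.08 ± 0.24) among them, and 4 did not. Of 11 mesenchymal genes 6 rose in both channels and 5 did not, with Cdh2 (2.69 ± 0.25 and 1.98 ± 0.32) among those that rose. Of 8 BMP targets 4 rose in both and of 5 paraxial mesoderm genes 4 rose in both. Of 13 pluripotency genes 4 fell in both channels, 1 rose and 8 did neither; those that fell were Dppa5a, Gdf3, Zfp42 and Dppa3 (-2.37 ± 0.25 and -2.23 ± 0.29), and Tbx3 rose. Of 7 primitive streak genes 3 rose in both, Hand1, Eomes and Mesp2 (2.42 ± 0.15 and 0.70 ± 0.17), and Gdf3 fell.

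In the green channel 111 probes passed for day 3 against day 2 (43 rose), 343 for day 4 against day 3 (177 rose) and 936 for day 4 against day 2 (451 rose); in the red channel the counts were 157, 272 and 1021, and 80, 153 and 667 probes passed with the same sign in both. For day 3 against day 2 the share that rose was 38.7% in the green channel, 53.5% in the red channel, 72.9% of the 48 probes past the test among those above the median intensity and 20.0% of the 20 past a test for a minimum of 1.5-fold. The 3 counts of the green channel fell to as few as 51 without day 2 replicate 1, 182 without day 4 replicate 3 and 518 without day 4 replicate 3. Other left-out samples that moved the first count by over 1.5 times were day 2 replicates 2 and 3 (72 and 55) and day 3 replicates 1 and 3 (73 and 68). For the others they were day 3 replicate 3 and day 4 replicate 2 (224 and 213) for the second, and day 2 replicates 1 and 3 and day 4 replicate 2 (547, 585 and 554) for the last.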

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

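The tests of a constant dye effect for the day 4 genes and for the glycolysis list, of the size kept by the day 4 genes within print blocks, and the correlations of the day 3 ratio, were chosen after their results were seen. Intervals in this section are from a bootstrap over probes or genes with the arrays held fixed. They leave out the spread between arrays and treat probes as independent. The ratios of the genes and lists given in the next paragraph differed between days in a test of the difference itself (limma for genes, camera for lists), with day differences on the log2 scale of the red over the green channel.

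From day 2 to day 3 the differences were Nrp 2.36, Ctla2a 2.35, Dkk1 2.27, Gata4 1.87, Cdh2 1.85, Ndr2 -1.46, Cldn3 -1.27, Uchl1 -1.26, Bnip3 -1.26 and Igfbp5 -1.04. From day 3 to day 4 they were Cdh2 -2.57, Uchl1 1.91, Igfbp5 2.02, Tdo2 1.77, Spp1 1.66, Serinc5 1.53, Upp1 -3.14, Mesp2 -2.71, Tdgf1 -2.67 and Podxl -2.45. From day 2 to day 4 they were Ctla2a 2.91, Tdo2 1.77, Upp1 -3.39, Tdgf1 -2.35, Podxl -3.38, Ttr 1.56, Hbb-y 1.56, Ccnd2 -2.90 and Eomes -2.26, and for the panel Pdgfra -0.94, Gata1 1.42 and Pou5f1 -1.69. Nrp, Ctla2a, Tdo2, Hbb-y, Igfbp5, Gata1 and Pdgfra were not well above background in a channel on at least 1 of the days compared, so that their values are differences of fitted ratios and no measured sizes. The lists past the test between day 2 and day 4 had median differences of 0.43 (BMP targets), 0.32 (epithelial), -0.40 (glycolysis and hypoxia), 1.18 (hematopoietic), -1.40 (Nodal and activin targets) and -0.21 (primitive streak). With an estimated correlation only the glycolysis and Nodal lists passed, with adjusted p = 0.130 for BMP targets, 0.0901 for epithelial and primitive streak and 0.0668 for hematopoietic genes.

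At day 2, 230 dim probes were lower in the red channel, with a median log2 ratio of -0.74, and 53.5% of them lay in print blocks 21 to 25, which hold 10.4% of all gene probes. With loess within each print block their median kept 0.812 of its size (bootstrap interval 0.79 to 0.93), which argues against a trend over print blocks as the whole cause. That fit removes only what spots of a block share at a given intensity, so an effect of single spots inside a block was not tested. On the day 4 arrays the median ratio of these probes kept 0.689 of its size (0.62 to 0.81). This passed the bound set beforehand for a constant dye effect, though a fully constant effect would keep its whole size. The probes were picked by their low day 2 ratios, so part of the shrinkage may come from that choice. A lasting difference between DOX and control samples, or a fixed effect of single spots, would look the same. The design, with dye and treatment confounded, cannot separate them. Spots without signal in either channel made up 25.2% of these probes (20.0 to 30.0), and 76.5% were under the limit in the red channel, so that absent signal may account for part of the pattern. On each array fewer gene probes of all kinds passed the limit in the red than in the green channel.

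At day 4, 136 probes differed by over 1.5-fold, 81 higher and 55 lower; 3 of 7 hematopoietic and 2 of 15 epithelial genes were among the higher ones, and 3 of 7 Nodal and activin targets among the lower ones, though none of these 3 lists passed at day 4 with an estimated correlation and other lists were split, as paraxial mesoderm with 1 higher and 2 lower. For these 136 probes, and not for the other day 4 calls, a constant dye effect is argued against by the 88.2% of them that also passed for day 4 minus day 2 with the same sign. The probes were picked by their day 4 ratios, which also enter that difference, so the choice itself may raise this share. A trend over print blocks is argued against by a median ratio that kept 0.980 of its size (0.95 to 1.01) with loess within print blocks. The 100% that kept sign and call there decide nothing, as that fit called more probes in all (2869 against 2656). The idea that a sample of each array was ahead in the same course of differentiation was tested through the correlation across probes of the day 4 ratio with the change of both channels from day 2 to day 3: Spearman's rho was 0.0112 (-0.0060 to 0.026) over all probes, -0.026 over those above the median intensity and -0.018 over the 2656 past the test. By the bound set beforehand this would count against a lead, but that bound was wrong, since a lead at day 4 shows in later changes, which were not measured, and the day 3 ratio went with the change from day 2 to day 4 (rho 0.17 over all probes, 0.38 over the 3070 past the test) and the day 2 ratio hardly with that from day 3 to day 4 (0.033 over all probes and 0.055 over those above the median intensity, but 0.34 over the 503 past the test), so that a lead stays open. A difference in lineage between DOX and control samples stays open too; which sample held which genes rests on the unsettled direction.

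The glycolysis and hypoxia list was lower at day 3 and day 4. A constant dye effect is argued against by its median day 4 minus day 2 difference of -0.40 (-0.62 to -0.32). A trend over print blocks is argued against by a day 3 median that kept 0.91 of its size (0.75 to 1.08) with loess within print blocks. A difference in metabolism between DOX and control samples, such as oxygen supply within the embryoid bodies, was not tested.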

How the results depend on the processing

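Print-block loess, the signal-to-noise filter, single-band clones and the red channel as control were chosen after seeing the data. Over all alternatives 136 counts of probes or lists stayed within 1.5 times the reported one and 69 did not; of named genes and panel values 4060 kept direction and side of the threshold, 696 lost the call, 4 gained it and 3 reversed, all in genes not called: T at day 2 without day 2 replicate 1 (-0.066, against 0.079 without replicate 3), T at day 3 without day 3 replicate 1 (-0.0039, against 0.16 without replicate 3) and Gata1 at day 2 without day 2 replicate 2 (-0.12, against 0.16 without replicate 3). The median of all probes stayed within 0.1 of 0 with median centring, scale normalization, plain subtraction and print-block loess, which hold it there by construction, and with the value table (-0.041 at day 4).

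The day 2 count of 503 was 122 with plain background subtraction, 1598 with scale normalization between arrays, 245 for probes above the median intensity, 294 with day 2 arrays alone and 157 with the value table. The day 3 count of 3070 was 1809 with scale normalization and 1921 with day 3 arrays alone. Print-block loess gave 743 for day 3 minus day 2 in place of 489. A minimum of 1.5-fold (limma treat) gave 52, 158 and 136 at days 2, 3 and 4, 18 for day 3 minus day 2, 121 for day 4 minus day 3 and 84 for day 4 minus day 2, and 20, 115 and 273 for the time course. With it the share of higher probes was 30.8% at day 2, 59.6% at day 4, 83.3% for day 3 minus day 2 and 46.3% for day 4 minus day 3, against 41.9, 45.7, 40.3 and 59.8%, and the share that rose in the time course was 20.0, 63.5 and 54.9% against 38.7, 51.6 and 48.2%. In the time course, probes above the median intensity gave 48 (day 3 against day 2) and 493 (day 4 against day 2), and the arrays of the days compared alone 65 (day 3 against day 2) and 198 (day 4 against day 3). Fewer probes tested or fewer arrays belong to these alternatives by construction; otherwise the cause was not tested.

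Lists past the test at day 3, 8, were 4 with plain subtraction, 2 for bright probes, 3 with the value table and 5 with the signal-to-noise filter. Those at day 4, 7 higher and 3 lower, were 3 and 3 for bright probes and 3 and 4 both with plain subtraction and with the value table. Those at day 2, 3, were 1 with the value table, and those for day 4 minus day 2, 6, were 3 with the signal-to-noise filter. An estimated correlation gave 0, 5, 1 and 2 lists (day 2, 3, 4 and day 4 minus day 2), and fry 6, 15, 16 and 14.

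Both samples of an array are a block in the ratios; with no replicate block the counts were 77, 151 and 155 at days 2, 3 and 4, and 2, 42 and 29 for day 3 minus day 2, day 4 minus day 3 and day 4 minus day 2, with 14.3, 28.5 and 48.4% higher at days 2, 3 and 4 against 41.9, 45.4 and 45.7%, and 100, 35.7 and 62.1% upward for the differences against 40.3, 59.8 and 52.0%. Across days no pairing of the samples by number was seen. In the green channel, deviations from the day mean correlated over 0.1 in 3 of 9 same-numbered pairs and 6 of 18 others, with highest values of 0.43 and 0.41. With 3 samples per day the deviations are not independent, so this check is weak. With the replicate block day 3 against day 2 in the time course gave 69 in place of 111.

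Leaving out 1 array gave 204 to 352 at day 2, 1596 to 2798 at day 3, 1145 to 2136 at day 4, 238 to 538 for day 3 minus day 2, 689 to 1085 for day 4 minus day 3 and 590 to 974 for day 4 minus day 2. In the time course it gave 51 to 87, 182 to 373 and 518 to 782. Lists ranged from 2 to 3 at day 2, 7 to 8 at day 3, 7 to 9 at day 4 and 6 to 9 for day 4 minus day 2. The Mixl1 level, the values without background correction, the value table in the time course and a slide or scan batch were not run, for want of a probe, of a separate background, of a common scale between days and of a known batch.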

Other observations

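Rps7, Dnaja2 and Adprh fell alike in both channels from day 2 to day 4 (-6.85, -6.58 and -4.40 in the green channel, -6.36, -6.01 and -4.11 in the red channel). Both channels come from the same arrays, so a difference between the arrays of those days would look the same. The calls in the authors' tables were recovered in part: of 449 probes called up by the authors at day 4, 435 were higher and 0 lower, and of 773 called down, 503 were lower and 0 higher. At day 3, 290 of 304 and 493 of 631 were recovered, and at day 2, 75 of 112 and 67 of 98.

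Other splits of the arrays were too few to reach a share under 0.05. For the comparison of a day, turning the sign of single arrays gives 4 splits, of which 1, the real one, gave as many calls: 503 at day 2, 3070 at day 3 and 2656 at day 4, against at most 0, 0 and 2 in the others, and 3, 8 and 10 lists against at most 2, 2 and 0. For differences between days the 6 arrays make 10 splits, of which 1, the real one, gave as many: 489, 1003 and 1000 probes for day 3 minus day 2, day 4 minus day 3 and day 4 minus day 2, against at most 0 each, and 6 lists against at most 3. For the time course 1 of 10 splits gave as many: 111, 343 and 936 against at most 0, 1 and 1.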
